A study of Homo sapiens with 6 samples.

How the data were processed

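RNA sequencing libraries from HepG2, an established human liver carcinoma cell line, were analysed after 48 h in 10 µM oridonin, a diterpenoid from the plant Isodon rubescens, or in 0.1% DMSO. The labels give no DMSO content for the oridonin samples. There were 3 libraries per treatment, and 6 in all. Each table column was tied to a library by the column name that the labels give for that library, and all per-sample columns of the tables belonged to the 6 libraries.

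The first table used held raw counts per gene for 60504 Ensembl genes, whole numbers with no scaling, as deposited by the authors. The second held log2 FPKM values (fragments scaled by gene length and library size) for 18404 genes, as deposited by the authors. These 18404 genes were exactly those with at least 1 count in each of the 6 libraries, and no pseudocount had been added. Within a library, the deposited log2 FPKM values followed from the counts and the deposited gene lengths with a single constant, whose coefficient of variation over genes was at most 0.201%. That constant did not equal the plain column total. Per the submitters' processing notes, the genome build was hg38 and DESeq2 1.10.1 was used. The aligner, the counting program and the strand setting are not given in the sources used here. Reads shared by near-identical genes, overlapping genes or antisense partners could therefore have been assigned to either, and values of such genes are uncertain, though not each of them is marked where it is named. Of the genes named, those that overlap a tested gene with at least as high a mean CPM in DMSO or oridonin are ACAT2, ACSM3, ACTA2, ANGPTL4, DDIT3, EGFR, FANCI, HOXD1, IDH3G, INHA, PSMC5, TUBA1A and ZFAS1, each on the opposite strand, and AHRR and UGT1A6 on the same strand. This comparison was made after the data were seen. Coordinates are those of the authors' deposited annotation columns on hg38.

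Gene symbols came from a table of current names for 41209 of the 60504 genes and otherwise from the deposited annotation or the GENCODE annotation. Of the 15116 genes tested, 15115 had a symbol. Total counts per library ran from 22250202 to 30739574, and the tested genes took between 99.888% and 99.922% of the counts of a library. The labels name no molecular identifiers, so reads are not independent molecules, and floors based on 3 counts cover counting error only. Pairs of libraries within a treatment differed far beyond sampling noise, so no library was counted as a repeat of another. The labels describe 3 wells or samples per treatment and do not say whether they came from separate cultures. The p-values thus measure only the spread between these samples, which may be technical.

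The counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, then glmQLFTest), with treatment as the only term. Genes were kept by filterByExpr at its defaults, and libraries were scaled by the trimmed mean of M values (TMM). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. A second count also asked for a log2 fold change of at least 1 in size, which is 2-fold. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values are counts scaled to library size with TMM factors, and means are given with the SD over 3 libraries. The sums for immunoglobulin constant genes and gut epithelial genes are instead CPM of total counts, without TMM factors. Principal components and Pearson correlations used log2 CPM with a prior count of 2.

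Before the data were examined, 47 gene lists with 1033 symbols were fixed from general knowledge of liver, stress and cell cycle biology, including markers of other cell types. Of the symbols, 1031 matched a gene and 907 were tested. Some genes, such as PHGDH, PSAT1, HK2, DDIT4 and C3, stand in more than 1 list, so lists that share members are not separate evidence. Lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1 on voom values, with an inter-gene correlation preset to 0.01 and adjustment over the 47 lists. Camera with a correlation estimated per list, and fry, which asks whether the genes of a list move on balance in 1 direction, stood beside it. The rule for the genes named was also fixed beforehand. It takes the 12 highest and 12 lowest log2 fold changes among called protein-coding genes with a mean of at least 10 CPM in the higher group and no overlap between the groups. It adds, for each list, up to 3 called members with the smallest p in the direction with more calls and 1 in the other direction, and 16 genes chosen for the treatment and cell line whatever their outcome. Where no member of a list was called, up to 2 with the highest mean were taken, and where space required, fewer were named. Some genes that the rule takes are not reported here. Genes named outside this rule, such as PIGR beside the immunoglobulin genes, were chosen after their values were seen.

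The gene test was checked on simulated counts with the means and library sizes of these libraries, 200 altered genes and 14888 genes tested. For oridonin against DMSO it recovered 63.3% of genes altered 1.25-fold, 74% of those altered 1.5-fold, 83.3% of those altered 2-fold and 100% of those altered 4-fold, and 4.88% of its calls were false. The simulated genes all took the dispersion of the trend, with no spread of their own around it. The altered genes were also a far smaller share than the 41.9% called in the real data. These rates may therefore differ in the real data. In a simulation with 14923 genes, the list tests found 2 of 2 lists shifted by 0.3 on the log2 scale and none of the 45 others. Its genes were drawn independently of one another, so it could not show how often correlated lists are called falsely. In the real data the estimated correlation was, for example, 0.291 for mitosis and G2/M genes. It was below the preset 0.01 for p53 targets (-0.0313) and endoplasmic reticulum chaperones (0.00969). Their camera p still rose, from 1.12e-07 to 0.00416 and from 8.34e-07 to 0.00781. A higher correlation thus does not by itself account for the calls lost with an estimated correlation.

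Alternatives fixed beforehand were DESeq2 size factors in the edgeR fit, scaling by total counts only, DESeq2 1.42.0, limma-voom, limma on the deposited log2 FPKM values, no low-count filter, a filter of 1 CPM in 3 libraries, a replicate block, leaving out each library, an adjusted p under 0.01, glmTreat against a log2 fold change of 1, an estimated correlation and fry. A filter of a mean of at least 10 CPM was added after the data were seen, as were 5 lists: gut epithelium, EGF family, ERK feedback, AHR targets, and insulin-like growth factor and inhibin axis. Figures were drawn with matplotlib.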

Results

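Transcript levels were measured by RNA sequencing in HepG2 cells, a human liver carcinoma line that keeps many hepatocyte functions. The cells had been treated for 48 h with 10 µM oridonin or with 0.1% DMSO, with 3 libraries each, and whether the oridonin wells held the same amount of DMSO is not stated in the labels. Total counts were 22250202, 29352396 and 28536857 in DMSO libraries 1 to 3 and 30739574, 30052040 and 27674586 in oridonin libraries 1 to 3. No single gene took more than 1.49% of a library. The series title names the metabolic action of oridonin as the question, and the only comparison the design holds is oridonin against 0.1% DMSO at 1 dose and 1 time.

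After 48 h of oridonin, HepG2 cells had lower levels of transcripts for secreted plasma proteins, coagulation and complement, DNA replication, mitosis, serine and one-carbon metabolism, and cholesterol and fatty acid synthesis. With an estimated correlation camera kept only the first 2 (adjusted p = 0.042 each), against adjusted p = 0.129 for replication and for mitosis, 0.0743 for serine and one-carbon metabolism, 0.259 for cholesterol and 0.172 for fatty acids. Levels were higher for NRF2 targets, p53 targets, conjugation enzymes, proteasome subunits and autophagy and lysosome genes (adjusted p = 0.0661, 0.0652, 0.238, 0.172 and 0.278 with an estimated correlation). Albumin (ALB), the main plasma protein, fell from 6864 ± 341 to 4025 ± 305 CPM (SD, n = 3), and the proliferation marker MKI67 fell from 245 ± 12.5 to 131 ± 6.96 CPM (SD, n = 3). TXNRD1, the cytosolic thioredoxin reductase and an NRF2 target, rose from 315 ± 0.306 to 865 ± 21.9 CPM (SD, n = 3). CDKN1A, which encodes the cell cycle inhibitor p21, rose from 185 ± 17.0 to 390 ± 14.7 CPM (SD, n = 3).

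Of the 15116 genes tested, 6332 (41.9%) were called by edgeR's quasi-likelihood test, 3118 higher and 3214 lower with oridonin. The median size of the log2 fold change among called genes was 0.38, and 714 called genes changed at least 2-fold, 472 upward and 242 downward. The split between genes higher with oridonin and genes lower with oridonin depended on the scaling: with total counts only, 4487 were called higher and 2359 lower, so that 65.5% of calls were upward against 49.2% with TMM scaling. The groups did not overlap in 51.6% of tested genes, where chance gives 10%. The 1st principal component took 65.0% of the variance and separated oridonin from DMSO, and correlations between libraries were 0.992 to 0.9956 within treatments and 0.978 to 0.9857 between them. Most of the genes changed at least 2-fold were expressed at a low level: 558 had a mean CPM under 10 in both groups and 156 had a mean of at least 10 CPM in the higher group. Weakly expressed genes with an uneven level among the libraries were among them, such as PIGR at 0.245 ± 0.134 CPM in DMSO and 4.10 ± 2.18 CPM in oridonin (SD, n = 3). The same unevenness held for immunoglobulin constant genes, which averaged 9.69 CPM of total counts in DMSO and 64.0 in oridonin. The number fell to 175 when glmTreat tested for a change beyond 2-fold.

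**Figure D1:**
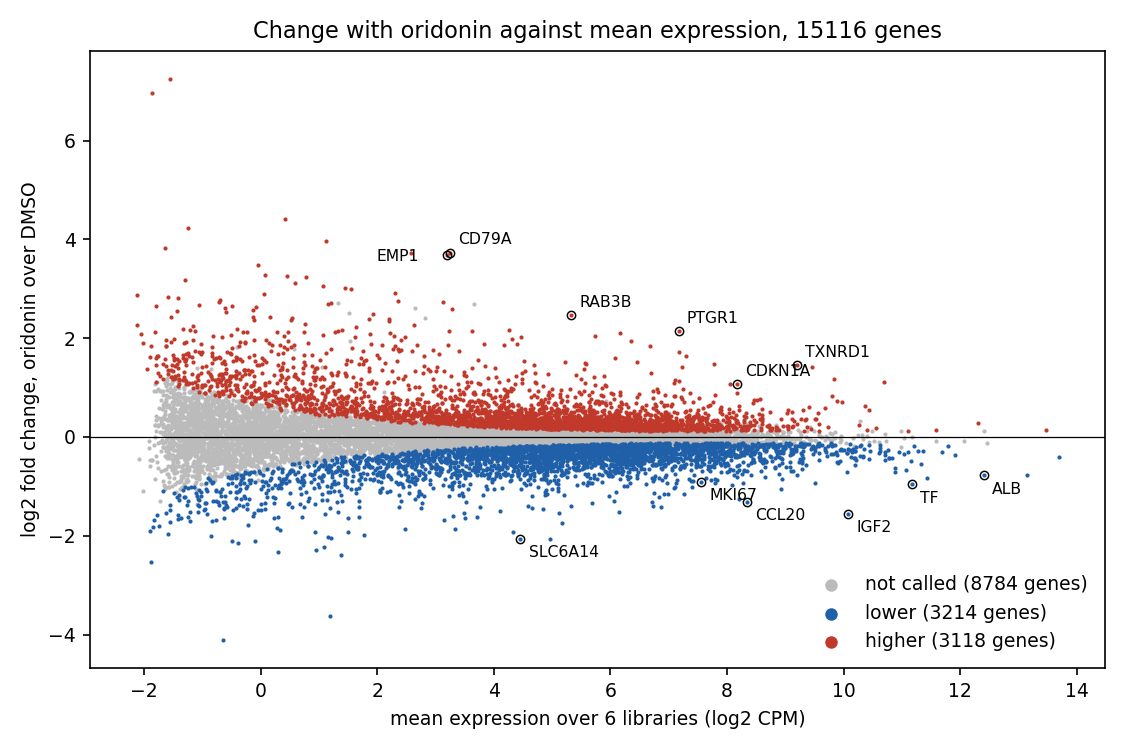
Log2 fold change of oridonin over DMSO (vertical axis) against mean expression over 6 libraries in log2 CPM (horizontal axis), 1 point per tested gene, with 3118 genes called higher in red, 3214 called lower in blue and uncalled genes in grey. Circles mark genes named in the text, among them RAB3B at 2.46 and IGF2 at -1.55.

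Among genes with at least 10 CPM in the higher group, CD79A had the highest log2 fold change, 3.73 ± 0.15 (SE, n = 3 per group, edgeR adjusted p = 1.38e-11). CD79A (ENSG00000105369, hg38 chromosome 19, 41877120 to 41881372, plus strand) encodes a signalling chain of the B cell receptor, and its level rose from 1.33 ± 0.154 to 17.7 ± 2.70 CPM (SD, n = 3). MMP3, a secreted matrix metalloproteinase, rose by a log2 fold change of 3.73 ± 0.16 and the membrane protein gene EMP1 by 3.69 ± 0.13 (SE). RAB3B (ENSG00000169213, hg38 chromosome 1, 51907956 to 51990764, minus strand), a small GTPase of vesicle traffic, rose 5.51-fold to 67.9 ± 1.56 CPM (SD, n = 3). PTGR1, a reductase of prostaglandins and reactive alkenals, rose 4.43-fold to 235 ± 7.63 CPM, and CAPN2, a calcium-dependent protease, rose 4.31-fold to 117 ± 3.54 CPM. JCAD, WNT7B, GPRC5A, GGT5 and PLAUR, the urokinase receptor, rose by log2 fold changes of 2.60, 2.28, 2.17, 2.15 and 2.14.

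Among genes with at least 10 CPM in the higher group, the lowest log2 fold changes belonged to SLC6A14, an amino acid transporter, at -2.06 ± 0.09, and to the homeobox gene HOXD1 at -2.06 ± 0.10 (SE). HOXD1, ACSM3 and INHA overlap a gene on the opposite strand, so their values are uncertain without a known strand setting. SLC6A14 fell from 35.4 ± 2.34 to 8.46 ± 1.07 CPM (SD, n = 3, edgeR adjusted p = 3.12e-11). ACSM3, KANK4, SSC4D and SERPINA11 fell by log2 fold changes of -1.93, -1.74, -1.64 and -1.50. SLC30A10, a manganese exporter, fell at -1.86, and EPO, the gene of erythropoietin, at -1.68. The inhibin genes INHA and INHBE fell at -1.63 and -1.51, and the interleukin 1 receptor antagonist gene IL1RN at -1.61. IGF2 (ENSG00000167244, hg38 chromosome 11, 2129112 to 2141238, minus strand), a fetal growth factor that HepG2 expresses at a high level, fell from 1614 ± 8.90 to 551 ± 24.1 CPM (SD, n = 3, log2 fold change -1.55 ± 0.05, edgeR adjusted p = 6.38e-13).

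Of 24 measured NRF2 targets and glutathione supply genes, 21 were higher and 1 lower, with a median log2 fold change of 0.63 (camera adjusted p = 1.62e-12; adjusted p = 0.0661 with an estimated correlation). The gene called lower was PIR, at -0.22, and it was not called in 7 of 15 other settings. TXNRD1 rose by 1.45 ± 0.05 and AKR1B10, an aldo-keto reductase, by 1.48 ± 0.05 on the log2 scale (SE). AKR1C1 rose from 1045 ± 39.9 to 2267 ± 197 CPM (SD, n = 3), but its value and that of AKR1B10 are uncertain as far as reads are shared with close paralogs. NQO1, a quinone reductase, rose from 648 ± 22.2 to 834 ± 26.4 CPM, a log2 fold change of 0.36. HMOX1, the heme oxygenase often induced with these genes, did not pass the test, at 25.2 ± 1.73 CPM in DMSO and 24.3 ± 1.06 CPM in oridonin (SD, n = 3). Its log2 fold change was -0.05 ± 0.07 (SE, edgeR adjusted p = 0.608), and the sign was opposite, at 0.03, with total-count scaling.

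Conjugation enzymes attach polar groups to drugs and metabolites. Of 23 measured genes in the list named after them, 10 were higher and 1 lower (median 0.19, camera adjusted p = 0.00126, and adjusted p = 0.238 with an estimated correlation). The list also holds EPHX1, microsomal epoxide hydrolase, which is not itself a conjugation enzyme. EPHX1 rose from 86.2 ± 2.18 to 185 ± 3.41 CPM, and the glutathione transferase gene GSTA1 from 11.8 ± 0.693 to 34.2 ± 1.90 CPM (SD, n = 3), the latter uncertain because of close paralogs. UGT1A1, the bilirubin glucuronosyltransferase, was called at a log2 fold change of 2.73, a value that is uncertain because genes of its cluster share exons. SULT2A1, a sulfotransferase, fell by 0.60 on the log2 scale. Of 13 measured cytochrome P450 enzymes and partners, 4 were higher and 1 lower, and the list was not called (camera adjusted p = 0.0574). CYP1A1, which oxidises polycyclic aromatic compounds, rose from 15.2 ± 0.253 to 37.2 ± 1.88 CPM (SD, n = 3), and CYP4F11 and CYP3A5 rose by log2 fold changes of 1.40 and 0.92. CYB5A, called lower at -0.22, was not called with total-count scaling. CYP3A4 had 0 to 6 counts per library and was not tested.

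Drug transporters went both ways, with 6 of 18 higher and 5 lower, and adjusted over the list alone 6 higher and 6 lower. The multidrug resistance proteins ABCC2, ABCC3 and ABCC1 rose by log2 fold changes of 0.76, 0.63 and 0.44, while SLC47A1, an organic cation exporter, fell by 0.57. This list was not called (camera adjusted p = 0.776), and its test pointed upward although its median was -0.06 and its mean -0.04. Among 21 nuclear receptors of xenobiotic and lipid metabolism, 7 were higher and 8 lower (9 lower adjusted over the list alone; camera adjusted p = 0.665). The bile acid receptor NR1H4 fell from 51.1 ± 3.93 to 22.5 ± 1.01 CPM (SD, n = 3), and the aryl hydrocarbon receptor AHR rose by a log2 fold change of 0.47.

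The 2 lists that camera also called with an estimated correlation both held liver secretory genes. Of 21 hepatocyte secreted plasma proteins, 17 were lower and 1 higher, with a median log2 fold change of -0.66 (camera adjusted p = 1.48e-10, and 0.042 with an estimated correlation). Transferrin (TF) fell from 3047 ± 159 to 1565 ± 45.4 CPM, fetuin (AHSG) from 3545 ± 70.4 to 2007 ± 37.0 CPM, and the lipoprotein gene APOC3 from 42.0 ± 3.73 to 15.3 ± 0.675 CPM (SD, n = 3). ALB and AFP, the fetal counterpart of albumin, fell at -0.77 and -0.71, and APOA2, called higher at 0.19, was not called on the deposited log2 FPKM values. Of 24 coagulation and complement genes, 21 were lower and none higher, with a median of -0.59 (camera adjusted p = 2.57e-10, and 0.042 with an estimated correlation). Complement C3 fell from 2355 ± 37.9 to 1433 ± 37.3 CPM (SD, n = 3), and SERPINF2, a plasmin inhibitor, and C5 fell at -0.88 and -0.99.

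Among 15 acute phase proteins, 9 were lower and 4 higher, and adjusted over the list alone 5 were higher. The list was called lower (median -0.62, camera adjusted p = 0.0108; adjusted p = 0.343 with an estimated correlation). ORM1, whose reads can be confused with those of a near-identical copy, and HAMP, the iron hormone hepcidin, fell at -0.88 and -0.93, while the fibrinogen chain FGB rose at 1.23. Liver-enriched transcription factors were lower in 12 of 19 and higher in 2 (median -0.26, camera adjusted p = 0.00082; adjusted p = 0.228 with an estimated correlation). HHEX and FOXA1 fell at -0.85 and -0.61, and TBX3 rose at 0.38.

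All 30 measured mitosis and G2/M genes were lower, by a median log2 fold change of -0.51 (camera adjusted p = 8.6e-18; adjusted p = 0.129 with an estimated correlation). TOP2A, the topoisomerase of dividing cells, fell from 634 ± 46.2 to 350 ± 14.4 CPM, and cyclin A2 (CCNA2) from 120.0 ± 1.69 to 72.7 ± 1.62 CPM (SD, n = 3). Of 32 DNA replication and G1/S genes, 31 were lower (median -0.52, camera adjusted p = 9.46e-16; adjusted p = 0.129 with an estimated correlation). MCM3 and MCM2, subunits of the replicative helicase, fell at -0.69 and -0.65, and RRM2, a ribonucleotide reductase subunit, at -0.59. Homologous recombination and Fanconi anaemia genes were lower in 16 of 20, or 17 adjusted over the list alone (median -0.51, camera adjusted p = 5.1e-08; adjusted p = 0.238 with an estimated correlation). FANCI and the exonuclease gene EXO1 fell at -0.76 and -0.91.

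Of 24 measured p53 targets, 16 were higher and 1 lower, with a median of 0.32 (camera adjusted p = 5.27e-07; adjusted p = 0.0652 with an estimated correlation). CDKN1A rose by 1.07 ± 0.06 (SE), RRM2B, a ribonucleotide reductase subunit, by 0.69 and TIGAR by 0.60. MDM2, which encodes a ubiquitin ligase, rose at 0.45. CCNG1, the target called lower at -0.22, was not called with total-count scaling. GDF15 had a log2 fold change of 0.32 ± 0.15 (SE) and was not called (edgeR adjusted p = 0.14), but it was called without DMSO replicate 3, at 0.49, and in 3 other settings. Apoptosis regulators were higher in 15 of 31 and lower in 4, or 5 adjusted over the list alone (median 0.15, camera adjusted p = 0.0191; adjusted p = 0.244 with an estimated correlation). CFLAR, an inhibitor of caspase 8, CASP8 itself and the death receptor TNFRSF10A rose at 0.63, 0.55 and 0.59, and BIRC5, an inhibitor of apoptosis expressed in mitosis, fell at -0.49.

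Replication-dependent histone genes went the other way from the replication list. Of 10 measured, 9 were higher and none lower, with a median of 1.43 (camera adjusted p = 7.79e-06; adjusted p = 0.12 with an estimated correlation). H1-2 rose by a log2 fold change of 1.39 to 17.8 ± 1.65 CPM, H2AC6 from 2.59 ± 0.122 to 7.59 ± 0.575 CPM and H2BC4 from 0.514 ± 0.0300 to 2.25 ± 0.229 CPM (SD, n = 3). The genes of each histone family are near-identical, so values of single members are uncertain, and most replication-dependent histone transcripts lack a poly(A) tail.

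Cytosolic ribosomal protein genes were lower in 28 of 33 with none higher (median -0.25, camera adjusted p = 1.2e-09; adjusted p = 0.238 with an estimated correlation). RPS6, RPLP0 and RPL3 fell at -0.44, -0.34 and -0.31. Ribosome biogenesis and MYC targets were higher in 7 of 26 and lower in 5, and the list was not called (camera adjusted p = 0.691). In that list NOP16 rose at 0.36 and NPM1, a nucleolar chaperone, fell at -0.28. Proteasome subunits were higher in 18 of 27 with none lower (median 0.15, camera adjusted p = 4.45e-05; adjusted p = 0.172 with an estimated correlation). PSMD2, a subunit of the regulatory particle, rose from 427 ± 12.1 to 628 ± 13.3 CPM (SD, n = 3), and PSMC4 and PSMC5 rose at 0.33 and 0.29.

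**Figure D2:**
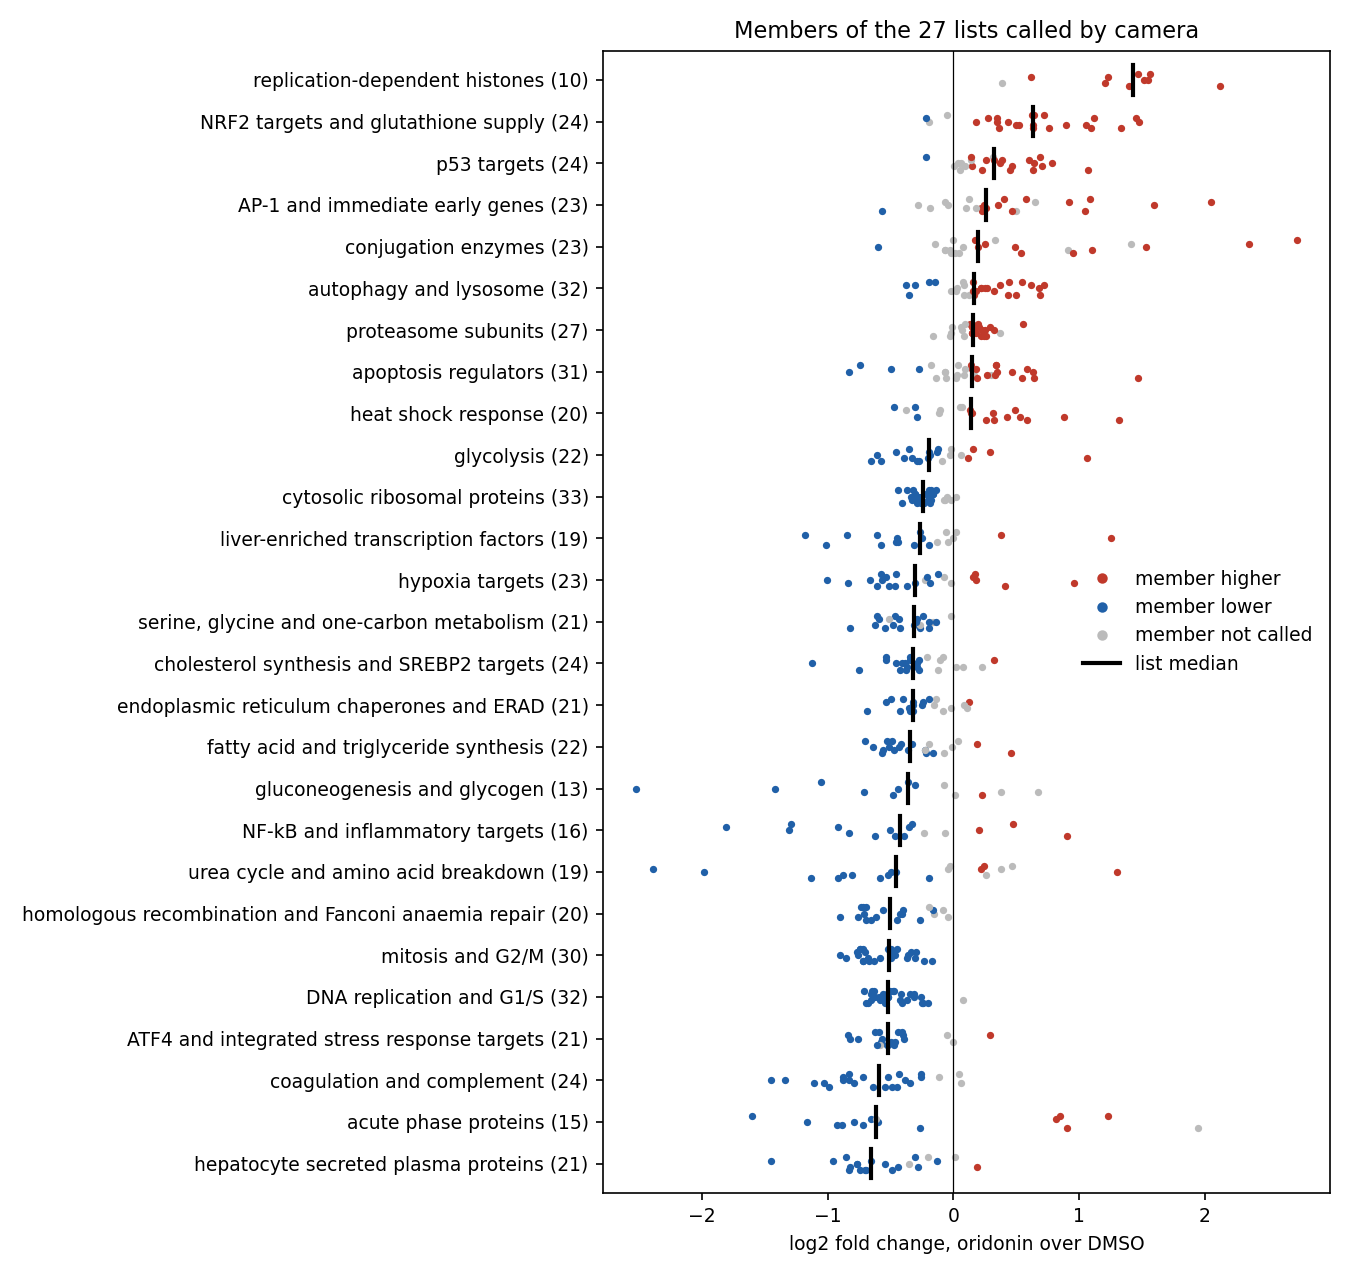
Log2 fold change of oridonin over DMSO (horizontal axis) for each measured member of the 27 lists that camera called (vertical axis, number of measured members in brackets), with members called higher in red, lower in blue and uncalled in grey, and list medians as black bars. Medians run from -0.66 for hepatocyte secreted plasma proteins to 1.43 for replication-dependent histones.

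Of 21 ATF4 and integrated stress response targets, 17 were lower and 1 higher, or 18 lower adjusted over the list alone (median -0.52, camera adjusted p = 3.06e-09; adjusted p = 0.172 with an estimated correlation). PHGDH and PSAT1, enzymes of serine synthesis, fell from 254 ± 13.1 to 143 ± 5.69 CPM and from 552 ± 19.1 to 357 ± 13.4 CPM (SD, n = 3). DDIT4 and DDIT3, the latter encoding the stress factor CHOP, fell at -0.84 and -0.76, and DDIT3 is uncertain because it overlaps a gene on the opposite strand. PPP1R15A, called higher at 0.29, was not called in 5 of 15 other settings. Endoplasmic reticulum chaperones and degradation genes were lower in 14 of 21 and higher in 1, or 15 lower adjusted over the list alone (median -0.32, camera adjusted p = 3.56e-06; adjusted p = 0.0734 with an estimated correlation). XBP1, a transcription factor of the unfolded protein response, PDIA4 and HSP90B1 fell at -0.69, -0.50 and -0.54, and DNAJB11, called higher at 0.12, was not called in 8 of 15 other settings.

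Heat shock genes were higher in 12 of 20 and lower in 3, or 4 adjusted over the list alone (median 0.14, camera adjusted p = 0.021; adjusted p = 0.172 with an estimated correlation). HSPH1 rose from 117 ± 1.93 to 164 ± 5.84 CPM (SD, n = 3) and HSPB1 fell at -0.47. HSPA1B and HSPA1A rose at 0.53 and 0.58, which is uncertain for each alone because the copies are near-identical. Autophagy and lysosome genes were higher in 19 of 32, or 20 adjusted over the list alone, and lower in 5 (median 0.17, camera adjusted p = 0.000331; adjusted p = 0.278 with an estimated correlation). The lysosomal proteases CTSB and CTSL rose from 719 ± 29.4 to 1183 ± 17.1 CPM and from 66.8 ± 1.59 to 108 ± 2.31 CPM (SD, n = 3), and LAMP2 fell at -0.31.

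Hypoxia targets were lower in 15 of 23 and higher in 5 (median -0.31, camera adjusted p = 0.000329; adjusted p = 0.125 with an estimated correlation). LOX, which crosslinks collagen, fell from 227 ± 13.6 to 113 ± 4.56 CPM (SD, n = 3), and ANGPTL4 rose at 0.96. Ferroptosis and iron genes were higher in 5 of 20 and lower in 6, or 7 adjusted over the list alone (camera adjusted p = 0.489). The cystine carrier gene SLC7A11 rose at 0.63, and SLC39A14, a metal importer, and ACSL4 fell at -0.52 and -0.53. Metallothionein and metal transport genes were higher in 5 of 9 and lower in 3 (camera adjusted p = 0.834). Their median was 0.19 while their mean was -0.10, and the test pointed upward. MT2A rose from 382 ± 59.6 to 1022 ± 28.7 CPM (SD, n = 3) and MT1E at 0.64, both uncertain because metallothionein genes are close paralogs, whereas SLC30A10 fell.

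Serine, glycine and one-carbon genes were lower in 17 of 21 with none higher (median -0.31, camera adjusted p = 6.41e-08; adjusted p = 0.0743 with an estimated correlation), with MTHFD2, a mitochondrial folate enzyme, at -0.60. PHGDH and PSAT1, given above with the ATF4 targets, also belong to this list. Urea cycle and amino acid breakdown genes were lower in 11 of 19 and higher in 3 (median -0.45, camera adjusted p = 0.00159; adjusted p = 0.125 with an estimated correlation). GLUD1, glutamate dehydrogenase, fell from 406 ± 4.54 to 215 ± 12.3 CPM and ASS1, argininosuccinate synthase, from 149 ± 13.5 to 67.6 ± 3.55 CPM (SD, n = 3). HPD, an enzyme of tyrosine breakdown, rose at 0.24.

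Cholesterol synthesis and SREBP2 targets were lower in 16 of 24 and higher in 1 (median -0.32, camera adjusted p = 6.94e-06; adjusted p = 0.259 with an estimated correlation). ACAT2, which acts at the start of the pathway, fell from 91.8 ± 1.27 to 54.4 ± 3.73 CPM (SD, n = 3), a value uncertain because genes on the opposite strand overlap it, and HMGCS1 fell at -0.54, while PMVK rose at 0.32. Fatty acid and triglyceride synthesis genes were lower in 15 of 22 and higher in 2, or 16 lower adjusted over the list alone (median -0.35, camera adjusted p = 8.99e-06; adjusted p = 0.172 with an estimated correlation). The desaturases SCD and FADS1 fell at -0.57 and -0.56, GPAM fell at -0.70 and LPIN1 rose at 0.46.

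Glycolysis genes were lower in 14 of 22 and higher in 4 (median -0.19, camera adjusted p = 0.00124; adjusted p = 0.238 with an estimated correlation). The glucose carrier SLC2A3 fell from 2627 ± 52.0 to 1662 ± 28.8 CPM (SD, n = 3), hexokinase HK2 fell at -0.61 and PFKFB4 at -0.58, while HK1 rose at 1.07. GAPDH, often used as a reference gene, fell at -0.36, and ACTB was not called (-0.09 ± 0.05 SE, edgeR adjusted p = 0.138) except with a replicate block. Gluconeogenesis and glycogen genes were lower in 8 of 13 and higher in 1 (median -0.36, camera adjusted p = 0.00282; adjusted p = 0.172 with an estimated correlation). The coactivator PPARGC1A fell at -1.42 and PGM1 at -0.71, and PC, pyruvate carboxylase, rose at 0.22.

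Other metabolic lists were not called by camera. Of those in this paragraph, fry called fatty acid oxidation and PPARA targets (fry adjusted p = 0.00697) and bile acid synthesis genes (fry adjusted p = 0.00414). Fatty acid oxidation and PPARA targets held 5 higher and 7 lower of 22 (camera adjusted p = 0.357), with FABP1 at -1.39 and CPT1A, which admits fatty acids to mitochondria, at 0.95. Bile acid synthesis genes held 2 higher and 3 lower of 11 (camera adjusted p = 0.561), with the FGF receptor partner KLB at -0.85, FGFR4 at -0.60 and BAAT at 1.37, and had a median of 0.03 against a mean of -0.03 and a downward test. Pentose phosphate and nucleotide genes held 4 higher and 5 lower of 21 (camera adjusted p = 0.834), with TALDO1 at 0.50 and IMPDH2 at -0.40, and had a median of -0.05 against a mean of 0.0061 and a downward test. Of 19 tricarboxylic acid cycle genes 1 was higher and 3 lower (camera adjusted p = 0.834), with citrate synthase (CS) at -0.46 and IDH3G at 0.27, and the median of 0.02 stood against a mean of -0.02 and a downward test. The other 2 called lower, FH at -0.20 and PDHB at -0.17, were each not called in 5 of 15 other settings. Nuclear-encoded oxidative phosphorylation genes held 8 higher and 3 lower of 32 (camera adjusted p = 0.665), with NDUFB3 at 0.53 and UQCRC2 at -0.18, the latter not called with total-count scaling. Of 13 mitochondrially encoded transcripts, MT-ND3 at 0.36 was the only one called (list camera adjusted p = 0.764), and the list median of -0.01 stood against a mean of 0.02 and an upward test.

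NF-kB and inflammatory targets were lower in 11 of 16 and higher in 3 (median -0.43, camera adjusted p = 0.000188; adjusted p = 0.172 with an estimated correlation). The chemokine gene CCL20 fell from 462 ± 29.9 to 186 ± 6.01 CPM, and TNFAIP3, a feedback inhibitor of NF-kB, fell at -1.30 to 38.5 ± 1.98 CPM (SD, n = 3). NFKBIA fell at -0.62 and CXCL8, the interleukin 8 gene, rose at 0.47. AP-1 and immediate early genes were higher in 13 of 23 and lower in 1 (median 0.26, camera adjusted p = 0.000416; adjusted p = 0.552 with an estimated correlation). DUSP5, a phosphatase of ERK kinases, rose from 20.6 ± 3.97 to 85.6 ± 1.92 CPM (SD, n = 3), DUSP4 and KLF6 rose at 1.60 and 0.47, and ATF3 fell at -0.57. Interferon-stimulated genes held 4 higher and 5 lower of 17 and were not called (camera adjusted p = 0.751), with OAS1 at 0.94 and IFIH1 at -0.78.

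Of 28 TGF-beta, matrix and epithelial-mesenchymal genes, 11 were higher, or 12 adjusted over the list alone, and 8 lower (camera adjusted p = 0.776). TIMP1, a metalloproteinase inhibitor, rose from 44.5 ± 5.19 to 160 ± 8.45 CPM (SD, n = 3), the collagen receptor chain ITGA2 rose at 0.78, and CCN2 fell at -1.03. WNT and liver stem-cell genes held 5 higher and 9 lower of 18 (camera adjusted p = 0.306), with KRT19, a keratin of bile duct cells, at 1.18 and CD24 and LGR5 at -1.14 and -0.64. Tubulin and cytoskeleton genes held 10 higher and 7 lower of 26 (camera adjusted p = 0.665), with TUBA1A and TUBB6 at 0.96 and 0.78 and TUBB at -0.47, and their median of -0.02 stood against a mean of 0.11 and an upward test. In the other 35 lists the counts adjusted over the list alone equalled those over all genes tested.

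**Figure D3:**
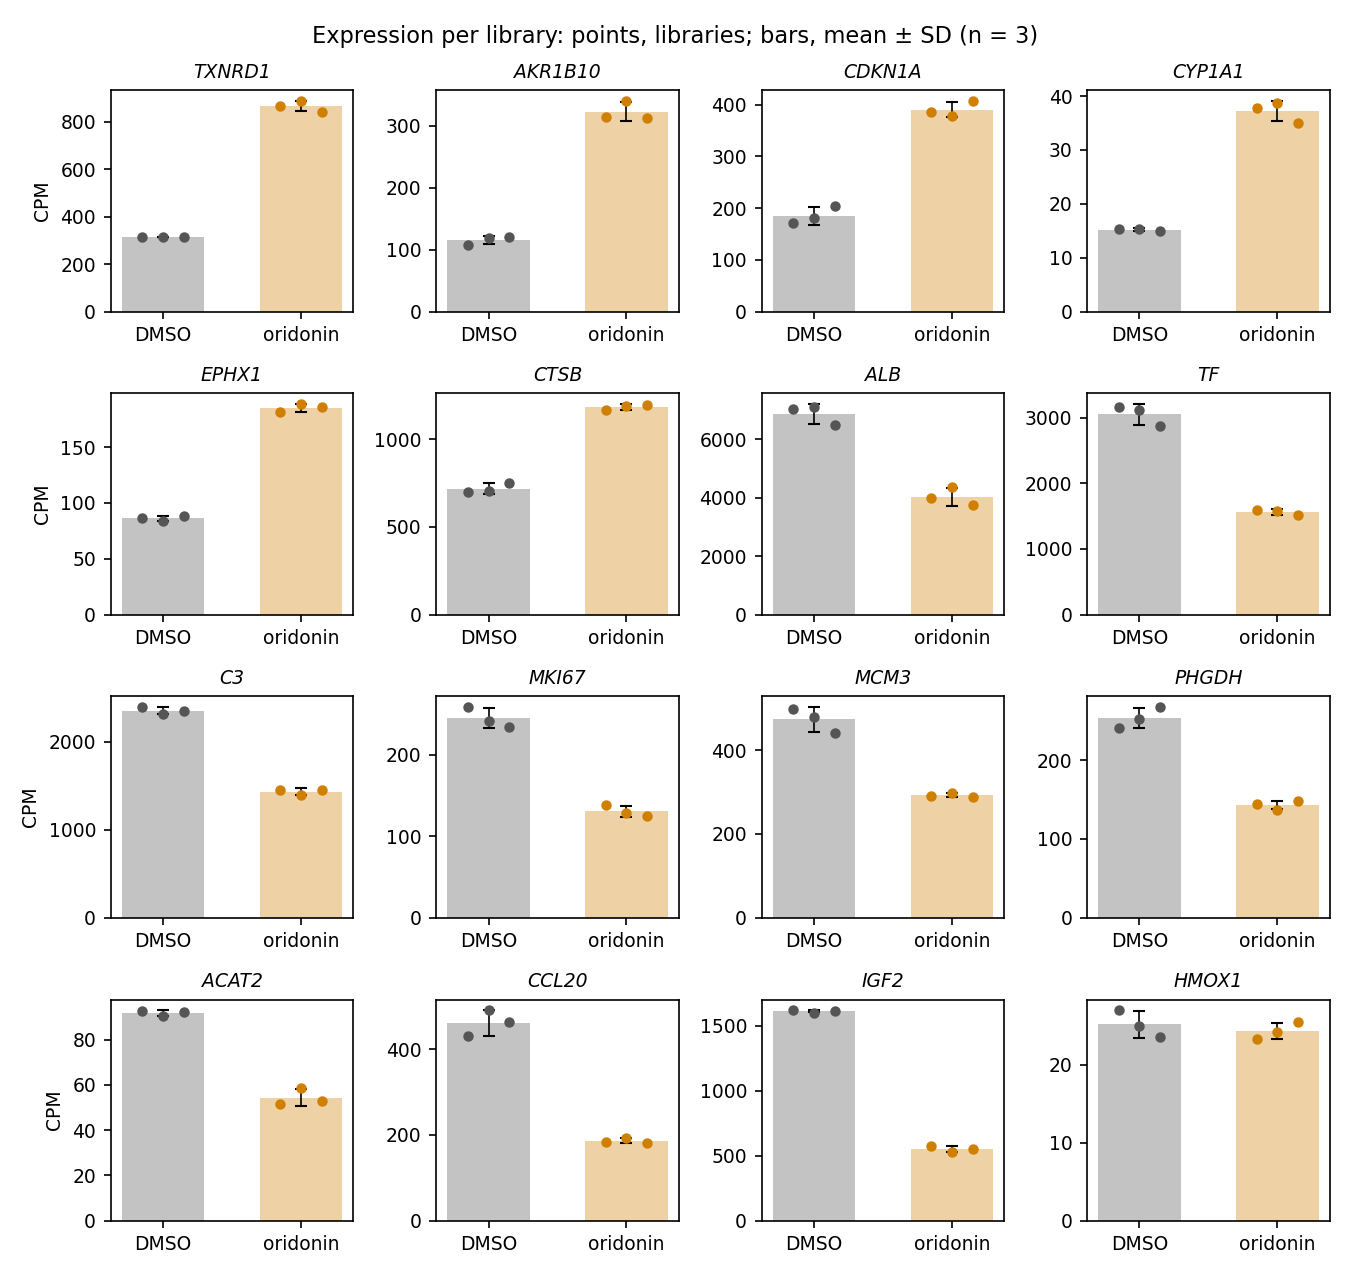
CPM after TMM scaling (vertical axes, from 0) of 16 genes in DMSO and oridonin libraries, with points for the 3 libraries, bars for the mean and error bars for the SD. The groups do not overlap for 15 of the genes, such as TXNRD1 with 315 and 865 CPM, and they do overlap for HMOX1 with 25.2 and 24.3 CPM.

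Camera called no list of markers of other cell types, while fry called the leukocyte markers (fry adjusted p = 0.00875). Leukocyte markers held 3 higher and 3 lower of 8 (camera adjusted p = 0.429), and their summed level of 500 to 797 CPM per library came mostly from lysozyme (LYZ), which fell at -0.68. LCP1, FCER1G and CD3D were called higher at 0.43, 0.84 and 0.47, FCER1G not without oridonin replicate 2 and CD3D not in 5 of the 14 other settings that tested it. Fibroblast and stellate markers held 2 higher and 1 lower of 5 (camera adjusted p = 0.834), with PDGFRB at -0.92, ACTA2 at 0.32 (not called in 2 of the 14 other settings that tested it) and summed levels of 47.1 to 77.4 CPM. Endothelial markers held 2 higher and 2 lower of 6 (camera adjusted p = 0.834) at summed levels of 7.23 to 10.1 CPM, with LYVE1 at 1.43 and CDH5 at -1.81, both under 1 CPM, and PECAM1 at 0.45, not called on the deposited log2 FPKM values. Markers of non-hepatic epithelial lines held 2 higher and 2 lower of 5 (camera adjusted p = 0.82), with summed levels of 304 to 413 CPM, mostly from VIL1, which fell at -0.39, while S100A2 rose at 0.88. Their median of -0.16 stood against a mean of 0.05 and a downward test. Immunoglobulin constant genes, which lay outside these lists, summed to 0.0449, 10.5 and 18.5 CPM in DMSO libraries 1 to 3 and to 26.97, 85.1 and 79.8 CPM in oridonin libraries 1 to 3. In the same libraries, a list of gut epithelial genes written after these reads were seen summed to 0.225, 4.53 and 4.38 CPM in DMSO and to 10.4, 23.8 and 21.5 CPM in oridonin. Unlike the marker sums, both are CPM of total counts without TMM factors. COL1A1, a fibroblast marker called at 1.14, and CDX2, an intestinal marker called at 1.61, were each not called in some settings, such as without DMSO replicate 2 for COL1A1, at 1.22, and without DMSO replicate 1 for CDX2, at 1.22.

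**Figure D4:**
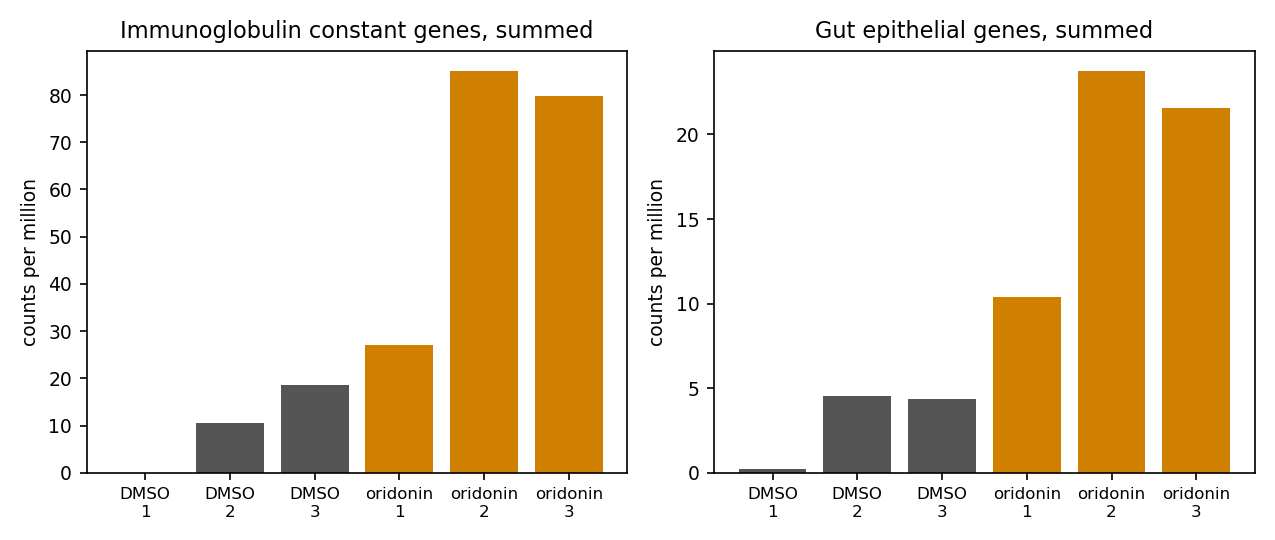
Summed CPM of immunoglobulin constant genes and of 12 gut epithelial genes (vertical axes, from 0) in each of the 6 libraries, with DMSO libraries in grey and oridonin libraries in orange. CPM here is of total counts, without TMM factors. DMSO library 1 has 0.0449 CPM of immunoglobulin constant genes, the other 2 DMSO libraries 10.5 and 18.5 CPM and the oridonin libraries 26.97 to 85.1 CPM.

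Camera with the preset correlation called 9 lists higher and 18 lower, fry called each of these 27 in the same direction, and an estimated correlation left 2. Fry called 11 lists higher and 21 lower in all. Its further calls include cytochrome P450 enzymes and drug transporters (fry adjusted p = 0.000115 and 0.000202), which camera did not call.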

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

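The tests of this part, apart from edgeR's gene test, were chosen after the result was seen. Transcripts of immunoglobulin and gut epithelial genes, most of them outside the fixed lists, stood above their level in the DMSO libraries. Immunoglobulin constant genes averaged 64.0 CPM of total counts in the oridonin libraries against 9.69 in the DMSO libraries, and a list of 12 gut epithelial genes written after these reads were noticed averaged 18.6 CPM against 3.05. Constant-region counts were 1, 308 and 529 in DMSO libraries 1 to 3 and 829, 2558 and 2208 in oridonin libraries 1 to 3, where 3 counts were taken as the floor, and IGHG1 alone had 0, 61 and 116 and then 130, 462 and 479 counts. The gut genes had 5, 133 and 125 counts in the DMSO libraries and 319, 714 and 596 in the oridonin libraries, among them CEACAM5 with 0, 19 and 34 and with 37, 105 and 69 counts. Of the immunoglobulin and gut genes, 13 were expressed enough to be tested, and edgeR's quasi-likelihood test called 4 of them, all higher. As a list, 5 measured gut genes held 3 called higher (median 1.78), and a list test decides nothing here because the genes were chosen after the reads were noticed. With 3 libraries against 3, an exact permutation test could not go below p = 0.1.

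Lower depth of DMSO replicate 1 is argued against, since at the rate of DMSO replicate 2 it would have given 233.5 immunoglobulin constant reads and it gave 1 (Poisson probability 9.4e-100, for counting error only). Induction by oridonin as the whole cause is argued against by the 529 such reads in DMSO replicate 3. Reads from another sample remain a candidate explanation: 55 different germline V genes had reads over the 6 libraries (6, 5 and 8 genes in DMSO libraries 1 to 3 and 12, 36 and 33 in oridonin libraries 1 to 3), and the gut reads of DMSO replicate 1 were 5 where its depth called for 99.2. V reads, at 9, 7 and 13 in the DMSO libraries and 21, 83 and 72 in the oridonin libraries, did not follow the constant-region reads among the DMSO libraries, which leaves this open. When such material entered, and why its share was higher in the oridonin libraries, was not tested, and CD79A does not follow these reads, with 1.37, 1.16 and 1.46 CPM in the DMSO libraries and 16.9, 15.5 and 20.7 CPM in the oridonin libraries.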

How the results depend on the processing

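The filter of a mean of at least 10 CPM was chosen after the data were seen, and all other settings were fixed before. The count of genes changed by oridonin was 6332 and ranged from 4565 at an adjusted p under 0.01 to 7689 with a replicate block, with 5323 by DESeq2, 6323 by limma-voom, 5338 by limma on the deposited log2 FPKM and 5282 to 6547 without 1 library; 5255 of the 6332 were shared with DESeq2 and 5477 with total-count scaling, all in the same direction. The count of genes changed at least 2-fold was 714, and it was 441 with a filter of 1 CPM in 3 libraries and 127 with a mean of at least 10 CPM, both of which test fewer weakly expressed genes, and 175 with glmTreat, which asks for more than a 2-fold change. With an estimated correlation, 0 lists were called higher and 2 lower, while the other 12 settings, fry included, kept all 27. Apart from fry, these settings all used camera with the preset correlation of 0.01, so they do not test that choice. Fry asks a different question and called more lists, 11 higher and 21 lower of 47. The share of variance on the 1st principal component was 65.0%, against 38.8% with no low-count filter, 75.9% with 1 CPM in 3 libraries, and 62.3% to 67.2% without 1 library. HMOX1, uncalled throughout, reversed from -0.05 to 0.0303 with total-count scaling, which itself moved the median of all genes from 0.0112 to 0.0915. Of 200 named genes 196 were called, 180 of these in each of the up to 15 settings that gave the gene a value, and 16 lost the call somewhere. The replicate numbers did not pair the libraries by the rule set, since deviations of same-numbered libraries correlated at 0.19, 0.07 and 0.17 and not all above 0.1, although each library correlated best with its own number, as a hint from the data; the replicate block kept 6325 of the 6332 calls and gave 748 genes at 2-fold. Of genes under 10 CPM 26.5% were called against 51.2% of the others, and how far depth limits this was not tested. Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 6332 genes and 714 at 2-fold. The highest of the others gave 0 of each. The others mix both treatments in each group, so the treatment difference adds to the spread within groups and their 0 decides nothing. For lists the real split gave 27 and the others 10 to 20. Camera with the preset correlation thus called lists in splits where no gene was called. In each of these splits the groups hold unequal numbers of libraries of each treatment. Part of the treatment difference thus remains between the groups, and the 10 to 20 lists do not measure false calls. Besides, 10 splits are too few for a share under 0.05 (1 split, the real one, reached each value).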

Other observations

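The tests in this part were chosen after the result was seen, except the draws of matched random lists, the gene test and the camera tests of lists fixed beforehand, and the genes named in the first 2 paragraphs were picked after their values were seen. EGFR, uncertain because an antisense gene overlaps it, rose from 6.08 ± 0.313 to 22.5 ± 1.18 CPM, while ERBB2 fell from 205 ± 8.23 to 130 ± 8.45 CPM and ERBB3 from 360 ± 6.72 to 182 ± 10.0 CPM (SD, n = 3). The ligand genes AREG and HBEGF rose at log2 fold changes of 0.63 and 0.50, and as a list 7 measured receptors and ligands held 3 higher and 2 lower and were not called (camera adjusted p = 0.675). Among genes of insulin-like growth factor and inhibin signalling, IGF2 fell at -1.55 and IGFBP1, FST and DLK1 at -0.49, -0.51 and -0.71, while IGFBP4 rose at 0.35. That list of 10 measured genes held 6 lower and 1 higher, but it was written after its members IGF2, INHA and INHBE were seen among the lowest genes, so its test decides nothing.

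Of 675 lincRNA genes, 130 were called higher and 53 lower, and of 747 genes annotated as antisense, 128 were higher and 38 lower, whereas 366 processed pseudogenes held 13 higher and 54 lower. Protein-coding genes held 2753 higher and 2987 lower of 12478. The 5700 genes with a mean CPM under 10 in both groups held 886 higher and 622 lower. UCA1 rose from 8.96 ± 1.20 to 33.1 ± 1.31 CPM, NEAT1 from 159 ± 21.9 to 286 ± 22.8 CPM and CCAT1 from 32.1 ± 1.45 to 61.0 ± 1.69 CPM (SD, n = 3). SNHG5 fell at -0.68, SNHG29 at -0.65, SNHG7 at -0.65, SNHG1 at -0.64, ZFAS1 at -0.73 and GAS5 at -0.33, and no list of such genes was tested. Because the strand setting is not known, values of antisense genes cannot be separated from those of their partners. Reads of pseudogenes may likewise be shared with near-identical genes.

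Replication-dependent histone transcripts were higher while DNA replication genes were lower, and summed histone levels were 19.4, 21.04 and 17.8 CPM in DMSO libraries 1 to 3 and 49.2, 49.8 and 44.6 CPM in oridonin libraries 1 to 3. Carry-over of RNA without poly(A) tails is argued against as the whole cause only as far as small RNA genes stand for such RNA. Pooled reads of small non-coding RNA genes differed by 0.056 on the log2 scale, with 9 pairwise ratios from -0.25 to 0.35. The histone median was 1.43. Carry-over of longer RNA without such tails was not tested. A larger share of cells in S phase is argued against as far as transcripts show it, since 31 of 32 DNA replication and G1/S genes were lower. Their median was -0.52, with members from -0.713 to 0.0735. This fall is part of the pattern itself and so is no separate test, and the share of cells in each phase was not measured. A general rise of weakly expressed genes is argued against: 0 of 10000 random lists matched on mean expression reached the histone median (0 percent), their central 95% running from -0.25 to 0.38. No other biological explanation was weighed, and reads shared among near-identical histone genes stay open.

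Cytosolic ribosomal protein transcripts were lower in 28 of 33, with members from -0.44 to 0.02 (camera adjusted p = 1.2e-09; adjusted p = 0.238 with an estimated correlation). Library scaling is argued against only as the cause of the gap to other genes. The list median of -0.25 with TMM lay -0.26 from the median of all genes, where the interquartile range of the members was 0.115. Scaling moves all genes alike, so this gap hardly changes between scalings and comparing them is no test. The size of the fall did depend on the scaling: with total counts the list median was -0.166. Random lists matched on length and expression had a median of -0.12, so a fall of short and highly expressed genes may account for part. Only the 33 list members were left out of these draws. Any ribosomal protein genes outside the list could be drawn, so the -0.12 does not show that such genes fall in general. A general fall is argued against as the whole cause, since 0.77 percent of 10000 such lists were as low, although genes of one complex vary together more than random ones do.

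A rise of targets of the aryl hydrocarbon receptor as a group may go with the higher CYP1A1 and AHR. Of 6 measured targets 5 were higher, with a median of 0.846 (camera adjusted p = 0.00304, over 5 lists; p = 0.0762 with an estimated correlation), and since the list holds CYP1A1 itself and shares NQO1 with the NRF2 targets, and AHRR and UGT1A6 are uncertain because each overlaps a more abundant gene on the same strand, the hypothesis stays open. A rise of ERK feedback genes as a group, prompted by DUSP5, DUSP4, FOSL1 and EGFR, is likewise open. Of 16 measured genes 5 were higher and 3 lower, with a median of 0.074 (camera adjusted p = 0.0701; p = 0.506 with an estimated correlation), and members such as ETV4 fell while DUSP6 was not called.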
